A study of Arabidopsis thaliana with 24 samples.

How the data were processed

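Small RNA was sequenced from inflorescences of Arabidopsis thaliana. The labels name 24 libraries in 8 genotype groups of 3: the wild type Col-0, the single mutants heso1-4, urt1-1, ski2-5 and rrp4-2, the double mutant heso1-4/urt1-1, and the triple mutants rrp4-2/urt1-1/heso1-4 and rrp4-2/urt1-1/dcl2CRISPR. Values per library were not used here, so neither the depth of each library nor the values of single replicates are known from the sources used here. The only data were the authors' deposited table of their own comparisons, with 28194 entries for 14888 loci in 13 mutant lines.

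Per the submitters' processing notes, the reads were handled with cutadapt 2.4, STAR 2.6.0a, featureCounts of Subread 1.6.3 and DESeq2 on the TAIR10 build; the notes give no order and no parameters. The signal in the authors' deposited table is a mean normalised count per locus, from 3.08 to 2.93e+06. It is the same in every line that lists a locus, which was checked for all 14888 loci, although the 8465 loci listed in 1 line could not differ. The log2 fold changes were made by the authors with DESeq2, per the file headers. The unadjusted p-value and the adjusted p-value of each entry were also deposited by the authors, and the largest adjusted p is 0.05. The table names no reference line. Col-0 is the only labelled line that it does not list as a mutant, and Col-0 is taken as the reference throughout.

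The 13 lines were matched to labels by name alone. This gave 5 lines with a label: urt1-1, ski2-5, rrp4-2, heso1-4/urt1-1 and rrp4-2/urt1-1/heso1-4. The line GKheso1 stands in for a heso1 single mutant, and the table does not state whether it is heso1-4. The lines rrp4urt1dcl2.B9 and rrp4urt1dcl2het are named for mutations of the labelled dcl2CRISPR group, and which of these lines that group is was not settled, so both were analysed. The ending het may mean that the dcl2 mutation is heterozygous there, which was not settled either. The lines ski2.2, urt1.2 and heso1.3 were used as second alleles. The lines ski2urt1dcl2.107 and ski2urt1dcl2.123 match no label and are treated in the closing part.

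A locus counted as higher or lower in a line when the deposited adjusted p was under 0.05, the authors' own p-value from DESeq2. The number of loci tested per line and the rank of each entry were recovered from the ratio of adjusted to unadjusted p. The table lists from 50.9% to 82.8% of the ranks up to the last rank past the threshold, so every count is a count of listed loci and a locus that is not listed is not shown to be unchanged. The missing entries were not analysed here. Among loci with p below 1e-20, 91 of 91 in ski2urt1dcl2.107 were listed in ski2urt1dcl2.123, 125 of 126 in rrp4urt1dcl2.B9 were listed in rrp4urt1dcl2het, and 83 of 89 in rrp4-2 were listed in rrp4-2/urt1-1/heso1-4. A setting of this recovery was changed after its first output gave too small a tested number for ski2.2 and GKheso1; on simulated data it returned 60000 of 60000 tested loci.

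Standard errors were recovered as the absolute log2 fold change over the normal quantile of the p-value. For 4 loci of rrp4urt1dcl2het the p is written as 0, and the median standard error of the locus in other lines was used. Over 6423 loci, the median log2 ratio of the largest to the smallest error of a locus was 0.0456. Relative to the other lines the error was 1.12 times as large in ski2urt1dcl2.107 and 0.989 to 1.04 times in the rest. For a locus not listed in a line, its detection limit there was taken as the normal quantile at the line's largest listed p times that standard error, scaled in the comparison of a pair by the median ratio of the errors of the 2 lines. A locus that is missing from the partial listing can lie above this limit, so results that use limits hold only where it does not. Lines were compared in 14 pairs by a two-sided z test on the difference of their log2 fold changes, over loci listed in both lines, with Benjamini-Hochberg adjustment. The shared reference libraries make this test cautious. On data simulated for rrp4-2/urt1-1/heso1-4 against rrp4-2, with 2249 loci, it called 55.0% of true differences of 1 and 93.1% of true differences of 2 on the log2 scale, and none of the 1955 unchanged loci. With a correlation of 0.5 between lines it called 81.9%, 97.9% and 0.409% of these.

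Before the data were examined, 14 lists with 204 entries and 5 lists taken from annotated locus types were fixed, and 19 lists stand for 494 tests of members called higher or lower. Each used Fisher's exact test (two-sided) against all other tested loci of the line. Only listed loci counted as called, so loci past the threshold that are missing from the table counted as not called. Every list member was taken as tested. If missing entries fall less often on a list than on other loci, the p-value of its enrichment is too small. The fixed lists are TAS loci, auxin receptor genes, superoxide dismutase genes, conserved microRNA target genes, phased-siRNA PPR genes, NB-LRR microRNA targets, tasiRNA target genes, mRNA loci known for 22-nt siRNAs in decay mutants, mutated genes, silencing machinery genes, RNA decay genes, photosynthesis genes, floral organ genes and pollen genes; the annotated types are microRNA, tRNA, snoRNA, snRNA and rRNA genes. The other 2 planned lists, plastid and mitochondrial loci, have no IDs in the annotation used, so their 136 loci in the table were counted with an exact sign test, a count added after the values were seen. The lists of histone genes, heat shock protein genes and copper-responsive microRNA genes were chosen after the values were seen, with 78 further tests. Benjamini-Hochberg adjustment ran over each family. Members were also adjusted over their list alone, with unlisted members taken as unchanged. These counts therefore cannot exceed those over all loci and cannot show members that the adjustment over all loci missed. For overlap of calls, 100 draws simulated unchanged lines that share their reference, with a correlation of 0.5. Such lines would hardly have calls at the threshold. The simulated overlaps thus treat every listed call as noise and do not measure the part due to the reference.

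Named loci followed a rule fixed before the data were examined: among loci past the threshold with a mean normalised count of at least 10, the 8 with the largest positive and the 4 with the largest negative log2 fold change per line, the 6 conserved microRNA targets with the smallest adjusted p, and up to 2 called members of every other list. Members of the TAS, auxin receptor, superoxide dismutase, 22-nt siRNA and mutated gene lists could be named in any comparison. Between lines, the 5 largest differences in each direction were taken. Gene names and coordinates come from the TAIR10.1 reference annotation, in which 8863 of the 14888 loci were found; 5889 transposable element loci have IDs of their own without coordinates. Coordinates count from 1.

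The alternatives tried were an adjusted p under 0.01, an absolute log2 fold change of at least 1, a mean normalised count of at least 10, leaving out structural RNA, microRNA and organelle loci, and a correlation of 0.5 in the difference test. Another 2 were added after the data were seen: collapsing overlapping loci, and testing loci listed in 1 line of a pair against the detection limit of the other. The planned count model, its alternatives, replicate checks and set tests with random lists need values per library or unlisted loci and were not run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.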

Results

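Inflorescence small RNA was compared between the wild type Col-0 and mutants of URT1 and HESO1, terminal nucleotidyl transferases that add nucleotides to RNA 3' ends. Other mutants affected RRP4, a core subunit of the RNA exosome, SKI2, a helicase that feeds the cytoplasmic exosome, and DCL2, a Dicer that makes 22-nt siRNAs. The labels give 3 libraries for each of 8 genotypes; the authors' deposited table holds 13 mutant lines, 14888 loci and no values of single libraries. Depth per library is therefore unknown, and how many libraries show a direction cannot be given. The question is how tailing and decay of RNA shape siRNA production from mRNAs and other loci. The values used hold no read lengths, so siRNAs of a given size are not told apart from other small RNAs. The deposited p-values and the z tests between lines rest on the spread between samples. Fisher's exact tests and exact sign tests count loci, and their p-values hold no such spread. The Fisher p-values also assume that missing entries fall alike on a list and on other loci, which was not checked. The sign ± marks a standard error (SE) recovered from the deposited p. A locus is higher or lower here when its deposited adjusted p was under 0.05; the table lists only part of such loci.

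**Figure D1:**
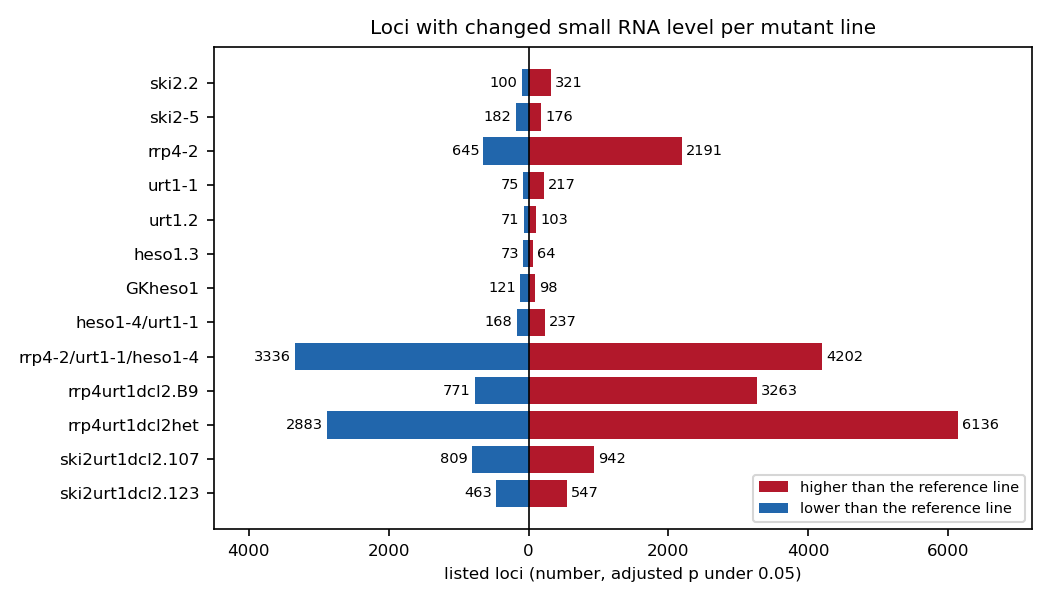
Number of loci listed with a higher (red, right) or lower (blue, left) small RNA level than the reference, for each of the 13 mutant lines (x axis: number of loci, adjusted p under 0.05). Lines that combine rrp4 and urt1 mutations list the most, with 6136 higher loci in rrp4urt1dcl2het.

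Of the mutated genes, URT1 (AT2G45620, TAIR10.1 chromosome 2, 18792864 to 18795904) had fewer small RNAs in each main line that carries urt1. In the authors' deposited table its log2 fold change was -1.31 ± 0.27 (SE) in urt1-1, -1.31 in heso1-4/urt1-1, -0.81 in rrp4-2/urt1-1/heso1-4, -1.12 in rrp4urt1dcl2.B9 and -0.84 in rrp4urt1dcl2het. HESO1 (AT2G39740, chromosome 2, 16575752 to 16579120) gave more small RNAs, with 4.60 ± 0.24 (SE) in GKheso1, 0.99 in heso1-4/urt1-1 and 1.14 in rrp4-2/urt1-1/heso1-4 in the authors' deposited table. DCL2 (AT3G03300) fell by 0.77 in rrp4urt1dcl2het in the authors' deposited table and was not listed in rrp4urt1dcl2.B9, where the detection limit was 0.64. SKI2 and RRP4 were listed in no line. These levels are of small RNA, not of mRNA, and part of a gene can still give reads in a mutant. Within the list of 5 mutated genes, the adjusted Fisher p was 0.036 for the fall in urt1-1 and 0.04 for the rise in GKheso1.

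In ski2-5, small RNAs rose at known microRNA targets and at the PPR genes that make phased siRNAs. Of 86 conserved microRNA target genes 12 rose and 0 fell, with a median log2 fold change of 1.37, and 74 were not listed. In the authors' deposited table AGO1, the main slicer of microRNA complexes, rose by 1.501 ± 0.19 (SE), the floral homeotic gene AP2 by 1.68, the leaf growth regulator TCP3 by 1.95, and the leaf polarity genes PHV and PHB by 1.43 and 1.503. Of the 17 PPR genes 11 rose (median 0.91), among them AT1G62590 by 1.04 and RPF2 by 0.99 in the authors' deposited table. The microRNA genes were split, with 10 higher and 11 lower of 326, and MIR845a and MIR845b fell by 3.01 and 2.75 in the authors' deposited table. The pollen pectin methylesterase genes VGD1 and VGDH1 fell by 2.02 and 1.45 in the authors' deposited table, the 2 of 6 pollen genes listed. The 12 NB-LRR microRNA targets held 2 that rose, AT5G43740 and AT1G51480, and 7 snoRNA genes rose with 1 lower, AT4G07635, at -4.10 in the authors' deposited table. Across the genome 176 loci were higher and 182 lower; protein-coding loci leaned lower, with 53 against 97. The largest positive value was that of AT5G43755, annotated as a reverse transcriptase-like gene, at 7.59, and the largest negative that of the transposable element AT3TE34145, at -9.87, in the authors' deposited table; AT5G43755 was listed in all 13 lines. Fisher's exact test gave an adjusted p of 2.4e-16 for the microRNA targets, 1.9e-23 for the PPR genes, 0.0034 for the NB-LRR genes, 0.0009 for the pollen genes and 9.7e-05 for the snoRNA genes. The counts adjusted over the list alone were 12, 11, 2, 2 and 7, equal to those over all loci, which they cannot exceed. The PPR genes are near-identical copies, so their reads can be shared and they are not independent.

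In rrp4-2, 2191 loci were higher and 645 lower. The microRNA-targeted TCP genes led the named targets: TCP3 (AT1G53230, chromosome 1, 19849788 to 19851725) rose by 4.30 ± 0.27 (SE), TCP2 by 3.63, TCP4 by 3.09 and the flowering regulator SPL4 by 3.07 in the authors' deposited table. In all 19 of the 86 microRNA targets rose (median 1.52), 3 fell and 64 were not listed. The copper/zinc superoxide dismutase genes CSD2 and CSD1, targets of miR398, were among those that fell, by 1.71 ± 0.29 and 1.34 ± 0.28 (SE) in the authors' deposited table. SMXL4 (AT4G29920, chromosome 4, 14632413 to 14636101), a phloem development gene, rose by 2.80 ± 0.52 (SE) in the authors' deposited table. It was the single listed member of the 4 mRNA loci known for 22-nt siRNAs in decay mutants. Structural RNAs moved apart. Many snRNA and tRNA genes exist as near-identical copies, so their reads can be shared and they are not independent, here and in the other lines. Of 82 snRNA genes 26 rose and 0 fell (median 1.25), and of 287 snoRNA genes 26 rose and 6 fell, whereas 26 of 672 tRNA genes and 4 of 11 rRNA genes fell and 0 rose. Among 326 microRNA genes 36 rose and 17 fell; MIR773b and MIR857 rose by 4.35 and 4.63 in the authors' deposited table. Small RNAs of 332 transposable element genes rose and those of 19 fell. The nuclear exosome helicase gene HEN2 rose by 0.91, the tasiRNA target ARF4 by 0.82 and the PPR gene RPF3 by 0.67, while TAS1B fell by 0.55, the floral organ gene PI by 0.71 and VGD1 by 0.85, in the authors' deposited table. The NB-LRR genes held 2 that fell and the photosynthesis genes 3 of 11, with RBCS1B at -0.81 in the authors' deposited table; 5 plastid loci were lower and 0 higher. Fisher's exact test gave adjusted p of 1.6e-09 for the rising microRNA targets, 0.0026 for the superoxide dismutase genes, 1.1e-16 for the snRNA genes, 0.0014 for the photosynthesis genes, 1.4e-07 for the tRNA genes and 3.7e-05 for the rRNA genes. The PPR genes, with 3 of 17 higher, did not pass as a list (0.11). Counts adjusted over the list alone were the same except for the tRNA genes, where 2 remained past the threshold.

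In urt1-1 the auxin receptor genes stood out: AFB3 (AT1G12820, chromosome 1, 4368760 to 4371298) rose by 1.41 ± 0.14 (SE) and AFB2 (AT3G26810, chromosome 3, 9867652 to 9870782) by 1.46 ± 0.15 (SE) in the authors' deposited table. Both are targets of miR393, and the other members, TIR1 and AFB1, were not listed. The plantacyanin gene ARPN rose by 1.77 in the authors' deposited table; 3 of 86 conserved microRNA targets were higher and 0 lower. None of the 17 PPR genes was listed. Of 326 microRNA genes 15 rose and 0 fell, with MIR5657 at 1.33 and MIR408 at 1.52 in the authors' deposited table, and the snRNA genes U6.5 and U6-29 rose by 0.88 and 0.73 there. Over all loci 217 were higher and 75 lower, with protein-coding loci at 78 against 23. The transposable element gene AT3G22955 had the lowest value, -8.65, in the authors' deposited table. The adjusted p of Fisher's exact test was 0.00057 for the auxin receptors, 0.02 for the microRNA targets and 7.1e-12 for the microRNA genes, with 2, 3 and 15 members adjusted over the list alone; the snRNA genes did not pass (0.15). AFB3, AFB2 and ARPN were the microRNA targets named here, so the results of the auxin receptor and microRNA target lists are not independent. Small changes were out of reach, since the largest unadjusted p listed in this line was 0.00037.

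In GKheso1, 23 of 326 microRNA genes rose and 0 fell (median 1.27), with MIR408 at 2.14 ± 0.23 (SE) in the authors' deposited table. TAS1B, a source of trans-acting siRNAs, fell by 0.82 ± 0.16 (SE) in the authors' deposited table. None of the 86 conserved microRNA targets, the 17 PPR genes that make phased siRNAs or the 82 snRNA genes was listed in this line. Of loci that the table types as microRNA targets, 1 was higher and 7 lower (exact sign p = 0.121 after adjustment), and AT1G28000, a PPR gene outside the list, was at -4.97 in the authors' deposited table. Over all loci 98 were higher and 121 lower, with protein-coding loci at 37 against 56 and transposable elements at 20 against 38. The adjusted Fisher's exact p was 2.3e-31 for the microRNA genes (23 adjusted over the list alone) and 0.074 for the TAS loci. Whether GKheso1 is the labelled heso1-4 is not stated, and its HESO1 value differs from that of heso1-4/urt1-1 (below).

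In heso1-4/urt1-1, 237 loci were higher and 168 lower. AFB3 and AFB2 rose by 1.08 ± 0.14 and 1.12 ± 0.16 (SE), NAC100 by 1.00, the PPR pseudogene AT1G62860 by 0.61 and the argonaute gene AGO3 by 1.24, while TAS1B fell by 0.79, in the authors' deposited table. Of 82 snRNA genes 13 rose and 0 fell (median 0.99), among them U1.5 at 1.28 in the authors' deposited table. Of the microRNA genes 27 rose and 2 fell, with MIR5657 at 1.82 and MIR408 at 2.03 in the authors' deposited table. Transposable elements leaned lower, with 40 higher and 79 lower. Fisher's exact test gave an adjusted p of 0.00063 for the auxin receptors and 0.023 for the 3 of 86 microRNA targets. The same test gave 1.1e-16 for the snRNA genes and 4.2e-27 for the microRNA genes that rose. Adjusted over the list alone, 2, 3, 13 and 27 members passed. AFB3, AFB2 and NAC100 were the microRNA targets named here, so the auxin receptor and microRNA target results are not independent.

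Adding the HESO1 mutation to urt1-1 was tested through the difference between heso1-4/urt1-1 and urt1-1, and GKheso1, which is not shown to carry the same heso1 mutation, was compared as well. Of 127 loci listed in both heso1-4/urt1-1 and urt1-1, 126 moved the same way and 4 differed. The overlapping noncoding loci AT1G09797 and AT1G09793 were higher in the double mutant by 1.299 and 1.296, AT5G20700 by 0.97, and AT3G24790, a protein kinase gene, was lower by a difference of -2.76 ± 0.40 (SE, adjusted p = 5.4e-10). AFB3 and AFB2 did not pass, with differences of -0.33 for both (adjusted p = 0.648 and 0.677). Against GKheso1, 8 of 121 shared loci differed; HESO1 itself differed by -3.62 and MIR5657 by 1.06, and 120 moved the same way. Directly between urt1-1 and GKheso1, 4 of 59 shared loci differed, again with AT3G24790 (2.66). With the shared reference counted as a correlation of 0.5, 14, 12 and 7 loci differed. These tests cover only loci listed in both lines, so a gene listed in 1 line alone is not shown to differ.

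In rrp4-2/urt1-1/heso1-4, 4202 loci were higher and 3336 lower. Histone genes held 6 of the 8 largest rises, among them AT3G53730 (chromosome 3, 19912385 to 19913515), by 8.12 ± 0.25 (SE), and AT5G65360, by 8.20 ± 0.39 (SE), in the authors' deposited table. In the histone list, chosen after these values were seen, 41 of 49 genes rose, with a median of 6.71; many are near-identical copies whose reads can be shared, so their number is uncertain. TCP3 rose by 4.90 ± 0.27 (SE), TCP4 by 4.25, TCP2 by 3.42 and SPL4 by 2.57 in the authors' deposited table, and 30 of 86 microRNA targets rose (median 1.14) with 1 lower, CSD2 at -1.17 there. Of 82 snRNA genes 46 rose and 0 fell (median 2.198), with U6acat at 3.73 and U1.10 at 3.33 in the authors' deposited table, and 58 of 287 snoRNA genes rose with 1 lower. AFB2 and AFB3 rose by 0.78 and 0.68, SMXL4 by 1.87, the nitrate reductase gene NIA2 by 1.07, ARF3 by 0.90 and HEN2 by 1.47, while TAS3C fell by 1.28, TAS1B by 0.90, the NB-LRR gene AT1G12290 by 0.51 and VGD1 by 0.82, in the authors' deposited table. None of the 17 PPR genes was listed. Protein-coding loci were higher at 2502 and lower at 440, whereas transposable elements were higher at 660 and lower at 2558. Of the microRNA genes 55 rose and 43 fell; 29 tRNA genes rose and 4 fell; 3 plastid loci fell. Fisher's exact test gave adjusted p of 1.7e-13 for the microRNA targets, 3.7e-31 for the snRNA genes, 1.7e-13 for the snoRNA genes and, among the later lists, 6.7e-40 for the histone genes; auxin receptors and 22-nt siRNA loci, with 2 of 4 each, did not pass (0.12 for both). The counts adjusted over the list alone were the same except for the tRNA genes, which fell to 0 in both directions.

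The line rrp4urt1dcl2.B9 showed 3263 higher and 771 lower loci. SMXL5 (AT5G57130, chromosome 5, 23144947 to 23149615) and SMXL4 rose by 6.66 ± 0.81 and 6.37 ± 0.52 (SE) and NIA2 by 1.14 in the authors' deposited table, so 3 of the 4 mRNA loci known for 22-nt siRNAs rose. Read lengths were not among the values used, so whether these small RNAs are 22 nt long is unknown. The cell wall enzyme gene XTH9 rose by 6.81 in the authors' deposited table. Of the 17 PPR genes 12 rose (median 1.09) and of 86 microRNA targets 26 rose (median 1.12) with 1 lower, CSD2; TCP3 rose by 3.78, AFB2 by 1.27, AFB3 by 1.14 and AGO1 by 0.62 in the authors' deposited table. Histone genes rose at 36 of 49 (median 3.19), snRNA genes at 30 of 82 (median 1.70) and snoRNA genes at 39 of 287 with 1 lower. Of the microRNA genes 45 rose and 13 fell, with MIR5657 at 3.47; ARF3 rose by 0.64, HEN2 by 1.55 and the floral organ gene SEP1 by 0.83 and VGD1 fell by 0.85, in the authors' deposited table. Only 3 tRNA genes were listed, all lower, and 3 plastid loci fell. The adjusted Fisher's exact p was 0.0041 for the 22-nt siRNA loci, 3.9e-11 for the PPR genes, 2.6e-12 for the microRNA targets, 1.4e-16 for the snRNA genes and 8.3e-35 for the histone genes; the auxin receptors did not pass (0.088). Counts adjusted over the list alone were the same for these lists, and 0 for the tRNA genes.

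The line rrp4urt1dcl2het showed 6136 higher and 2883 lower loci. The bromodomain genes GTE7 (AT5G65630, chromosome 5, 26225832 to 26229574) and GTE2 (AT5G10550) rose most, by 9.27 and 8.90, and the overlapping antisense locus AT5G01765 by 8.62, in the authors' deposited table, where their p is written as 0. SMXL5 rose by 7.21 ± 0.81 (SE), SMXL4 by 6.69 ± 0.52 (SE) and NIA2 by 1.13 in the authors' deposited table. PPR genes rose at 11 of 17 (median 1.67), histone genes at 41 of 49 with 1 lower (median of the risers 5.67), microRNA targets at 21 of 86 (median 1.18) with 5 lower, and snRNA genes at 30 of 82 with 1 lower. TCP3 rose by 4.17 and AFB2 and AFB3 by 0.73 and 0.51, while CSD2, CSD1 and AFB1 fell by 1.98, 1.75 and 0.58, in the authors' deposited table. Among other lists, the lower loci included 142 of 672 tRNA genes with 0 higher, 4 of 11 rRNA genes, 9 of 11 photosynthesis genes with RBCS1B at -1.03 in the authors' deposited table, and 101 of the 103 plastid loci in the table with 0 higher (median -0.74). Of the mitochondrial loci 8 were higher and 23 lower. No other normalisation was run, and a shift in the scale of this line would lower these lists together. The falls at tRNA, rRNA, photosynthesis and plastid loci are therefore not shown to be separate results. Transposable elements rose at 2378 and fell at 722 loci, transposable element genes rose at 1721 and fell at 43, and microRNA genes rose at 37 and fell at 56. TAS3, TAS3C and TAS1B fell by 0.43, 0.75 and 0.53, AGO4 by 0.61, the exosome nuclease gene RRP44A by 0.46, PI by 0.89, LFY by 0.94 and VGD1 by 1.06, and HEN2 rose by 1.19, in the authors' deposited table. The adjusted Fisher's exact p was 0.024 for the 22-nt siRNA loci, 5.9e-07 for the PPR genes, 0.00051 for the rising microRNA targets, 6.7e-33 for the histone genes, 2.6e-51 for the tRNA genes, 9.1e-10 for the photosynthesis genes, 0.038 for the superoxide dismutase genes, 0.03 for the TAS loci and 0.03 for the 3 of 8 floral organ genes. The NB-LRR genes, with 3 of 12 lower, did not pass (0.089), nor did the snoRNA genes, with 26 higher and 18 lower. Adjusted over the list alone 142 tRNA and 25 rising snoRNA genes passed, and the other counts were the same. The exact sign p after adjustment was 7.1e-30 for the plastid and 0.048 for the mitochondrial loci; loci of 1 organelle are not independent.

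**Figure D2:**
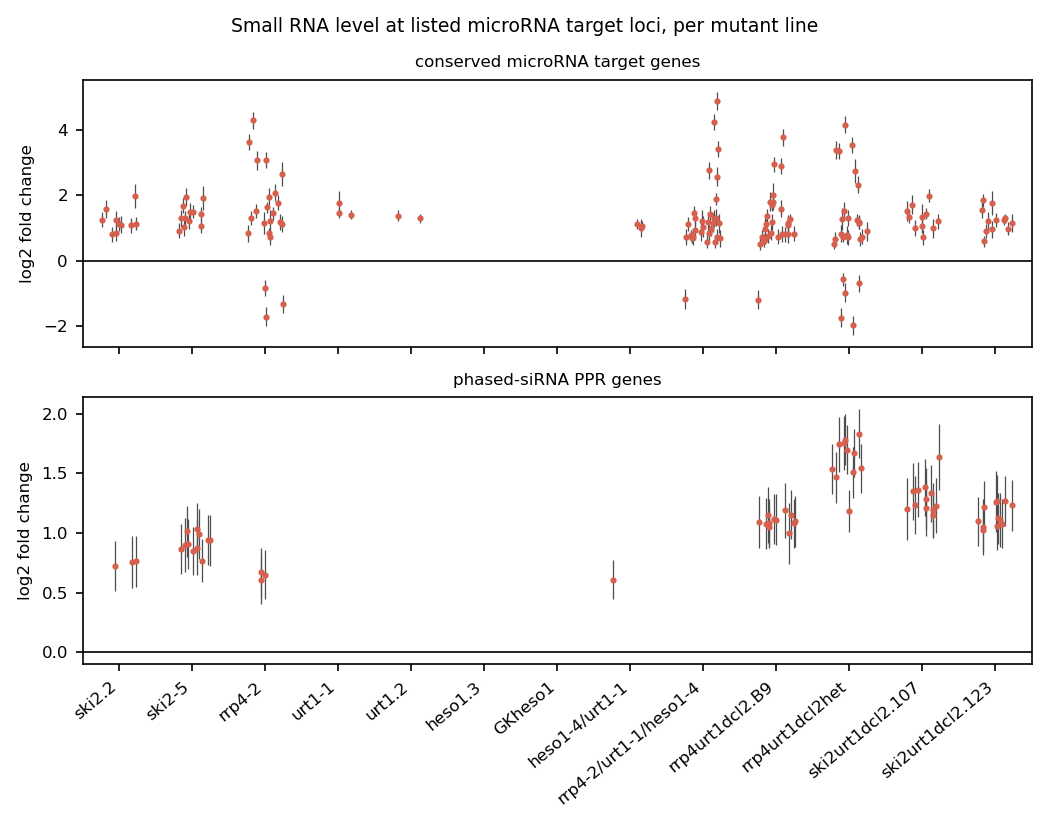
Log2 fold change of small RNA over the reference (y axis) at conserved microRNA target genes (top) and phased-siRNA PPR genes (bottom) in each of the 13 lines (x axis); points are listed loci and bars are standard errors recovered from the p-values. TCP3 is the highest point in rrp4-2/urt1-1/heso1-4 at 4.90, and PPR genes reach 1.83 in rrp4urt1dcl2het.

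Adding urt1 and heso1 mutations to rrp4-2 changed the size of many effects. Of 1457 loci listed in both rrp4-2/urt1-1/heso1-4 and rrp4-2, 1374 moved the same way and 275 differed, 147 higher and 128 lower in the triple mutant. The histone gene AT3G53730 differed by 7.22 ± 0.35 (SE) and TCP4 by 1.17 (adjusted p = 0.0051). At snRNA genes the difference was positive at 25 of the 26 shared loci, 20 of them called, with a median difference of 1.21. At transposable elements it was negative at 162 of 242 shared loci, with 64 called lower and 8 higher; the protein-coding gene AT5G53610 was lower by a difference of -4.90. If loci that are not listed lie under their detection limit, 628 loci differed, of which 372 were listed in rrp4-2/urt1-1/heso1-4 alone and 21 in rrp4-2 alone; the partial listing leaves open whether they do, here and in the counts with detection limits below.

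Against rrp4-2, 57 of 1837 shared loci differed in rrp4urt1dcl2.B9 and 122 of 2331 in rrp4urt1dcl2het. SMXL4 was higher than in rrp4-2 in both, by 3.57 ± 0.73 and 3.89 ± 0.73 (SE), and AT3G53730 by 4.74 and 6.81. The other histone gene shared with rrp4-2, HTA12, was called in rrp4urt1dcl2het (1.72) but not in rrp4urt1dcl2.B9, with a difference of 0.27 (adjusted p = 0.998). The fatty acid hydroxylase gene AT2G37700 was lower in both, by differences of -4.65 and -4.78. The 3 PPR genes shared with rrp4-2 were all called higher in rrp4urt1dcl2het, by a median of 1.06, and GTE2 by 8.21. In rrp4urt1dcl2.B9 the differences of these PPR genes were 0.48, 0.45 and 0.50 and none was called (adjusted p of the z test from 0.973 to 0.998). In rrp4urt1dcl2.B9 the gibberellin signalling repressor gene RGL1 was lower, with a difference of -2.13, and so was AP2, with -1.03 (adjusted p = 0.049). With a correlation of 0.5 the counts were 97 and 279, and with detection limits 102 and 396.

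Against rrp4-2/urt1-1/heso1-4, 247 of 2563 shared loci differed in rrp4urt1dcl2.B9, 86 higher and 161 lower, and 347 of 3003 in rrp4urt1dcl2het, 275 higher and 72 lower. SMXL4 was higher in both, by 4.50 ± 0.74 and 4.82 ± 0.74 (SE). Histone genes were lower in rrp4urt1dcl2.B9 at 36 of 36 shared genes, all called, with a median difference of -3.65, and HTA13 differed by -5.06. In rrp4urt1dcl2het the difference was negative at 41 of 41 with a median of -0.80, and 10 were called lower. GTE2 and GTE7 were higher in rrp4urt1dcl2het by 6.93 and 6.44, and the iron regulators bHLH38 and bHLH39 were lower, with differences of -2.67 and -2.54. At transposable elements the difference was positive at 713 of 872 shared loci, 155 of them called higher in rrp4urt1dcl2het and 3 lower. With a correlation of 0.5 the second count was 768, and with detection limits the first was 443.

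**Figure D3:**
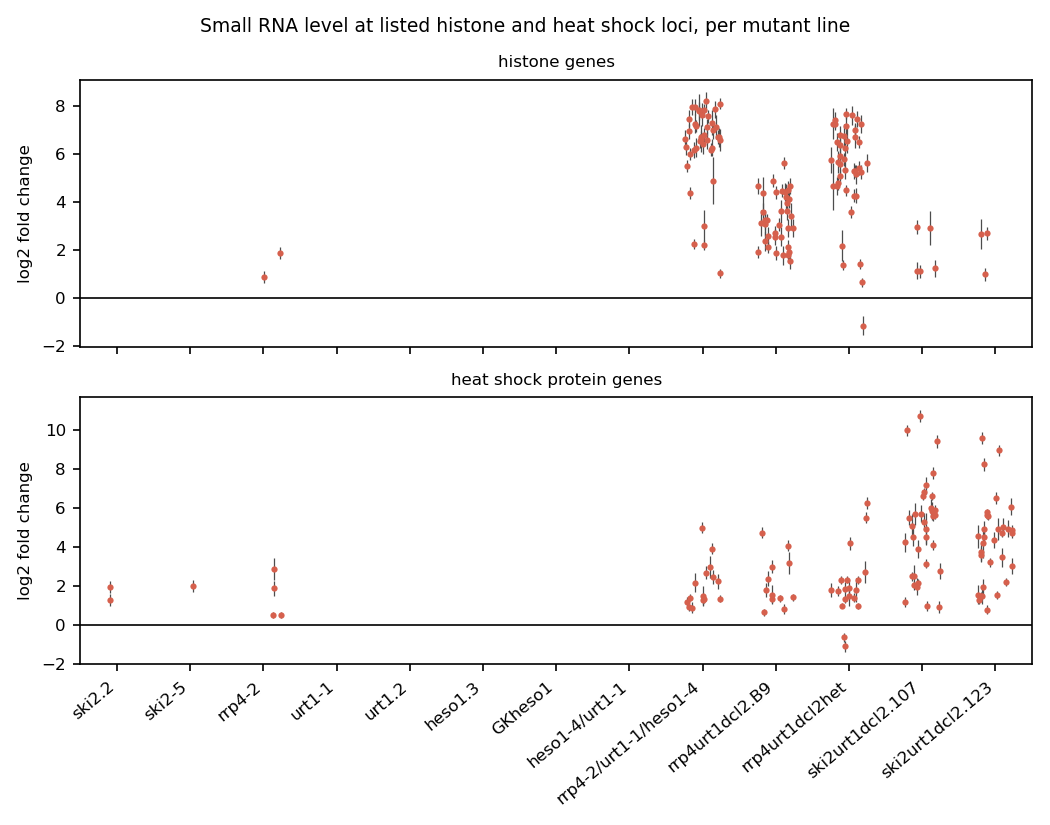
Log2 fold change of small RNA over the reference (y axis) at histone genes (top) and heat shock protein genes (bottom), lists chosen after the values were seen, in each of the 13 lines (x axis); points are listed loci and bars are standard errors recovered from the p-values. The median over listed higher histone genes is 6.71 in rrp4-2/urt1-1/heso1-4, 3.19 in rrp4urt1dcl2.B9 and 5.67 in rrp4urt1dcl2het.

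The decay mutants ski2-5 and rrp4-2 shared 128 listed loci, of which 123 moved the same way and 30 differed, 28 of them lower in ski2-5. TCP3 differed by -2.34 ± 0.39 (SE), MIR408 by -0.88 and the snoRNA locus AT4G07635 by -4.87. At conserved microRNA targets the difference was negative at 8 of 9 shared loci, with a median of -0.46. The 3 called were all TCP genes: TCP3, TCP2 (-2.33) and TCP4 (-1.87). The others ranged from -0.74 (ARPN) to 0.0015 (ARF10) and none was called. The shared PPR genes AT1G62910, RPF3 and AT1G63080 differed by 0.24, 0.24 and 0.22, none called. AT4G30740, a QWRF motif gene, was higher in ski2-5 by 2.32. At an adjusted p under 0.01, 15 loci differed, and with detection limits 143.

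The 19 microRNA targets that rose in rrp4-2 were followed into the multiple mutants. In rrp4-2/urt1-1/heso1-4, 14 were listed, 8 higher and 6 lower than in rrp4-2, with a median difference of 0.07 and 1 called higher, TCP4 (exact sign p = 0.79). In rrp4urt1dcl2.B9, 16 were listed, 2 higher and 14 lower, with a median of -0.30 and 1 called lower, AP2 (exact sign p = 0.0042). In rrp4urt1dcl2het, 14 were listed, 6 higher and 8 lower, with a median of -0.10 and none called (exact sign p = 0.79). Loci are not replicates, so the sign tests describe these loci. Over all loci higher in rrp4-2 outside microRNA genes the medians were 0.20, 0.09 and 0.17.

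At loci listed in both alleles of a gene the directions were the same, which shared reference libraries alone can also give. Between ski2.2 (321 higher, 100 lower) and ski2-5, 84 of 84 shared loci moved the same way and 0 differed by the z test, with 3 at an unadjusted p under 0.05 and 2 with a correlation of 0.5; AGO1 and TCP3 rose by 1.13 and 1.59 in ski2.2 in the authors' deposited table. Between urt1.2 (103 higher, 71 lower) and urt1-1, 81 of 81 moved the same way and 0 differed by the z test, with 1 at an unadjusted p under 0.05 and 1 with a correlation of 0.5; AFB3 and AFB2 rose by 1.297 and 1.38 in urt1.2 in the authors' deposited table. In ski2.2, 10 of 86 microRNA targets rose (Fisher's exact adjusted p = 1.9e-07) and 3 of 17 PPR genes (0.0046); in urt1.2, 7 of 82 snRNA genes rose (9.2e-10). The line heso1.3 had 64 higher and 73 lower loci, HESO1 was not listed there, and 7 microRNA genes rose (1.5e-07). Higher loci shared by ski2.2 and ski2-5 numbered 65, against 1.74 for independent lists and 27.85 in simulated unchanged lines with a shared reference. For urt1.2 and urt1-1 the numbers were 59, 0.330 and 10.9, and for heso1.3 and GKheso1 24, 0.0803 and 4.48.

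Overlaps of calls were larger than for independent lists, and part of the excess may come from the shared reference libraries. Unchanged lines would hardly have calls at this threshold, so the simulated numbers treat every listed call as noise. A number near or below them does not show that an overlap comes from the reference. Loci higher in both rrp4-2 and rrp4-2/urt1-1/heso1-4 numbered 1215, against 145 for independent lists and 716 in simulated unchanged lines with a shared reference. For rrp4-2 and rrp4urt1dcl2.B9 the numbers were 1637, 112 and 606, and for urt1-1 and heso1-4/urt1-1 they were 84, 0.759 and 18.9. For ski2-5 and rrp4-2 the 71 shared higher loci lay near the simulated 66.1, whose highest draw was 83, with 6.07 for independent lists. GKheso1 and heso1-4/urt1-1 shared 68 higher loci, against 0.333 and 11.2. Lower loci of rrp4-2 and rrp4-2/urt1-1/heso1-4 shared 159, below the simulated 239, and 83 loci were called in opposite directions in these lines.

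Several lists fixed before the data were examined held few calls in some or all main lines, and these are given with their adjusted p from Fisher's exact test. Among the 18 silencing machinery genes the smallest adjusted p was 0.222, for AGO1 alone in ski2-5, and the 16 RNA decay genes, with HEN2 in 4 lines, gave 1 in each. The 6 tasiRNA target genes, with ARF4 in rrp4-2 and ARF3 in 2 lines, gave 0.695 at the smallest. TAS loci passed in rrp4urt1dcl2het alone, with 0.343 in rrp4-2, 0.108 in heso1-4/urt1-1 and 0.274 in rrp4-2/urt1-1/heso1-4. The superoxide dismutase genes, which passed in rrp4-2 and rrp4urt1dcl2het, gave 0.568 in rrp4-2/urt1-1/heso1-4 and 0.183 in rrp4urt1dcl2.B9. Pollen genes passed in ski2-5 alone, and whether ski2-5 differs from other lines there was tested only at VGD1 against rrp4-2, where the difference was -1.18 and was called.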

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

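The tests of the loci listed in most lines, of the copper-responsive microRNA genes and of the photosynthesis genes, the summed limits in rrp4-2/urt1-1/heso1-4 and rrp4urt1dcl2het, and the expected numbers and the heterogeneity for the genes of ski2.2 were chosen after the results were seen. The grouping of histone genes by shared bases, the summed limits in rrp4urt1dcl2.B9 and the listing of the ski2.2 genes in ski2-5 were chosen before theirs.

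Differences between lines named for mutations of the same genes stood out in 3 pairs. Between heso1.3 and GKheso1, 4 of 45 shared loci differed (5 with a correlation of 0.5, 20 with detection limits for loci not listed), with LBD16 above in heso1.3 by 2.15 and MIR408 below, at -0.96; AT2G47020 overlaps MIR408 and its -0.95 is not a separate result. Between rrp4urt1dcl2.B9 and rrp4urt1dcl2het, 194 of 2966 shared loci differed, 5 above and 189 below in the former (435 with a correlation of 0.5, 255 with detection limits); GTE2 differed by -7.98, GTE7 by -6.89, 36 of 36 shared histone genes were below, all called, with a median of -2.76, and AFB3 was above by 0.62 (adjusted p = 0.034). Between ski2urt1dcl2.107 and ski2urt1dcl2.123, 4 of 808 shared loci differed (85 with a correlation of 0.5, 6 with detection limits), among them the heat shock gene HSP81-2 by 1.02. The labels do not say how the lines of each pair differ, and no explanation was tested for these differences. The name rrp4urt1dcl2het may stand for a heterozygous dcl2 mutation, so its DCL2 state may differ from that of rrp4urt1dcl2.B9.

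The lines ski2urt1dcl2.107 and ski2urt1dcl2.123, which match no label, stood out by heat shock protein genes: 34 of 69 rose in the former (median 5.20) and 32 in the latter (median 4.54), in a list chosen after the values were seen. In the authors' deposited table HSP70 was at 10.74 and 9.59 in these lines, SMXL4 at 6.27 and 5.87, and SMXL5 at 4.00 and 5.01. No biological explanation was tested.

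The histone genes were weighed first. Of 49 genes, 41 were higher in rrp4-2/urt1-1/heso1-4, 36 in rrp4urt1dcl2.B9 and 41 in rrp4urt1dcl2het. A general breakdown of abundant messenger RNA was tested for rrp4urt1dcl2het, where 9 of 11 photosynthesis genes were lower and 0 higher. By the rule of this test that goes against such a breakdown, but plastid loci fell there too, at 101 of 103 (median -0.74). No other normalisation was run, and a shift in the scale of this line would lower both, so the test cannot decide. An effect of the combined mutations beyond the sum of rrp4 and urt1 alone may account for most of the higher histone genes. Values lay above the summed values or limits of rrp4-2 and urt1-1 at 38 of 41 genes (92.68%) in rrp4-2/urt1-1/heso1-4. The same held at 37 of 41 (90.24%) in rrp4urt1dcl2het and 28 of 36 (77.78%) in rrp4urt1dcl2.B9, where the bound set beforehand was 80%. By more than their error, 38, 36 and 15 genes lay above it; the others stay undecided, a gene missing from the partial listing can lie above its limit, and the added heso1 and dcl2 mutations were not separated from this effect. Reads of a few source genes shared with their near-identical copies stay open as a source of part of the number, since the 41 genes of rrp4-2/urt1-1/heso1-4 form 4 groups with no stretch of 18 bases shared between groups, the largest with 31 genes.

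Loci listed in most lines were weighed second. In all 21 loci were listed in at least 11 of the 13 lines, 20 of them in 1 direction (16 higher, 4 lower), with AT5G43755 in 13 lines at a median of 7.53. Merging overlaps left 18 sets, but the 9 transposable elements among the 20 loci have no coordinates and could not be merged. The fold changes of the lines were alike, with a median heterogeneity of 0.8778 in units of that expected from the standard errors. This lies under the bound of 1 for values of the shared reference libraries at these loci as the source. Over the loci it ranged from 0.115 to 8.66, with 11 loci under 1, and the shared reference itself lowers it. A change common to all mutant lines would be alike as well, so an origin in the shared reference libraries stays open but is not shown. For the 7 copper-responsive microRNA genes, each listed as higher in most lines, the median was 1.949 (from 1.36 to 7.95). MIR398b and MIR398c have nearly the same values in each line. Counted as 1 gene, a choice made after the results were seen, they give a median of 2.86. That is past the bound of 2 against an origin in the shared reference libraries, so whether the bound is passed turns on how they are counted. All 7 genes lie above 1, although the shared reference lowers this value, which argues against reference values as the only source of the rise. A part from them cannot be told apart from a response of the mutants or from a property of single lines, which was not tested. Listed genes differed between alleles: all 7 rose in urt1-1 but 0 in urt1.2, and all 7 in ski2.2 but 2 in ski2-5. The partial listing leaves open whether the unlisted genes were unchanged. The genes shared by ski2.2 and ski2-5, MIR408 and MIR398a, differed by 0.17 and 0.06 and were not called.

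The transposable element genes higher in ski2.2, a line with no label, were weighed last: 109 rose there, with a median of 0.59. Of these, 97 were higher in rrp4-2, 102 in rrp4urt1dcl2.B9, 105 in rrp4urt1dcl2het, 59 and 41 in ski2urt1dcl2.107 and ski2urt1dcl2.123 and 20 in rrp4-2/urt1-1/heso1-4, but 5 in ski2-5, 7 in urt1-1, 3 in urt1.2, 1 each in heso1.3 and heso1-4/urt1-1 and 0 in GKheso1. Of the 66 genes above the detection limit of ski2-5, 4 (6.061%) were listed as higher there, under the bound of 20% set beforehand against both loss of SKI2 function in any allele and values of the shared reference libraries at these loci, and far from the 40.5 that the listed sizes would give. That bound was set wrongly, because the values lie close to the threshold at which they were picked: reference values alone predict 3.11 genes, and the same change in both alleles, corrected for this selection, 10.04, both under 20%. These explanations therefore cannot be told apart here, the heterogeneity (median 1.704, highest 19.3) decides neither way, and a property of the ski2.2 line itself also stays open and untested.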

How the results depend on the processing

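The test against detection limits, the collapse of overlapping loci and the lists of histone, heat shock and copper-responsive genes were chosen after seeing the data. No paired analysis was possible because no values per library were used here. Also not run, for want of values per library or of unlisted loci, were leaving out replicates, other splits of the samples, other normalisations and count filters, a second count model, a threshold of 0.1 and set tests with random lists; depth limits could not be measured. Loci with a mean normalised count of at least 10 gave 0.853 to 1 times the main counts, collapsed overlaps 0.75 to 1, and leaving out structural RNA, microRNA and organelle loci 0.765 to 1; none of these moved a count by over 1.5 times. Loci without coordinates, among them the 5889 transposable element loci, could not be collapsed, so overlaps that involve them are not covered. At an adjusted p under 0.01, 231 named loci stayed past the threshold and 30 did not, and 5 of 26 counts of list members fell by over 1.5 times: PPR genes to 0 in rrp4-2 (3) and heso1-4/urt1-1 (1), snRNA genes to 0 in urt1-1 (2), and microRNA genes to 9 in urt1-1 (15) and 24 in rrp4urt1dcl2het (37), with the main count in brackets. Fewer loci pass there by construction: higher loci numbered 113 (176) in ski2-5, 1450 (2191) in rrp4-2, 119 (217) in urt1-1 and 2720 (4202) in rrp4-2/urt1-1/heso1-4, with the main count in brackets. Lower loci numbered 244 (645) in rrp4-2, 77 (121) in GKheso1, 1995 (3336) in rrp4-2/urt1-1/heso1-4, 272 (771) in rrp4urt1dcl2.B9 and 1388 (2883) in rrp4urt1dcl2het, and 15 (30) loci differed between ski2-5 and rrp4-2. With an absolute log2 fold change of at least 1, again fewer by construction, higher loci numbered 1116 in rrp4-2, 120 in urt1-1, 2727 in rrp4-2/urt1-1/heso1-4, 1729 (3263) in rrp4urt1dcl2.B9 and 2821 (6136) in rrp4urt1dcl2het, and lower loci 184, 1124, 168 and 893 in the same lines without urt1-1. Of the list members, 10 of 26 counts fell by over 1.5 times at that fold change: microRNA targets to 17 (30), 14 (26) and 12 (21) in rrp4-2/urt1-1/heso1-4, rrp4urt1dcl2.B9 and rrp4urt1dcl2het, microRNA genes to 36 (55) and 28 (45) in the former 2, PPR genes to 2 (11) in ski2-5 and to 0 in rrp4-2 and heso1-4/urt1-1, and snRNA genes to 0 in urt1-1 and 6 (13) in heso1-4/urt1-1. A correlation of 0.5 narrows the error of a difference by construction: 14 (4) loci differed between heso1-4/urt1-1 and urt1-1, 97 (57) between rrp4urt1dcl2.B9 and rrp4-2, 279 (122) between rrp4urt1dcl2het and rrp4-2, 768 (347) between rrp4urt1dcl2het and rrp4-2/urt1-1/heso1-4 and 7 (4) between urt1-1 and GKheso1. With detection limits more loci are tested, and those not listed are assumed to lie under them: 14 differed between heso1-4/urt1-1 and urt1-1, 17 (8) between heso1-4/urt1-1 and GKheso1, 628 (275) between rrp4-2/urt1-1/heso1-4 and rrp4-2, 102 and 396 for rrp4urt1dcl2.B9 and rrp4urt1dcl2het against rrp4-2, 443 (247) between rrp4urt1dcl2.B9 and rrp4-2/urt1-1/heso1-4, 143 between ski2-5 and rrp4-2 and 23 between urt1-1 and GKheso1. The median difference from rrp4-2 of microRNA targets that rose in rrp4-2 was 0.07 in rrp4-2/urt1-1/heso1-4, -0.30 in rrp4urt1dcl2.B9 and -0.10 in rrp4urt1dcl2het; with targets chosen in ski2-5 they were -0.14 (reversed), -0.52 and -0.21, and with all loci higher in rrp4-2 outside microRNA genes the values were 0.20, 0.0912 and 0.17, reversed for the latter 2 lines; the cause was not tested.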

Other observations

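The test of the copper-responsive microRNA genes and the lists named here were chosen after the results were seen. Small RNAs of 7 copper-responsive microRNA genes, whose products limit copper proteins when copper is scarce, were higher in most mutants. All 7 rose in rrp4-2 (median 2.07), urt1-1 (1.52), GKheso1 (2.14), rrp4-2/urt1-1/heso1-4 (2.23), rrp4urt1dcl2.B9 (1.603) and rrp4urt1dcl2het (2.33), as well as in ski2.2 (1.36), ski2urt1dcl2.107 (1.18) and ski2urt1dcl2.123 (1.298), while 5 rose in heso1-4/urt1-1, 3 in heso1.3, 2 in ski2-5 and 0 in urt1.2. MIR398b and MIR398c, at 1.461 and 1.460 in rrp4-2 in the authors' deposited table and nearly the same in the other lines, may count the same reads, so the 7 genes are not independent. In the authors' deposited table CSD2 and CSD1, targets of 1 of these families, were at -1.71 and -1.34 in rrp4-2 and at -1.98 and -1.75 in rrp4urt1dcl2het. CSD2 without CSD1 was lower in rrp4-2/urt1-1/heso1-4 (-1.17) and rrp4urt1dcl2.B9 (-1.20). Neither was listed as lower in urt1-1 or GKheso1, where all 7 microRNA genes rose. Lower reference values may explain part of the rise. The median heterogeneity was 1.949, or 2.86 with MIR398b and MIR398c counted once. Its range from 1.36 to 7.95 over the 7 genes argues against reference values as the only source. A property of single lines was not tested and stays open, since the listed genes differed between alleles of URT1 and of SKI2.

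Heat shock protein genes also rose in the 3 lines that combine rrp4 and urt1 mutations. Of 69 genes, 15 were higher in rrp4-2/urt1-1/heso1-4 (median 1.49, adjusted Fisher's exact p = 0.00012), 12 in rrp4urt1dcl2.B9 (median 1.69, 0.00077) and 17 in rrp4urt1dcl2het (median 1.84, 0.00092) with 2 lower.

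The lines ski2urt1dcl2.107 and ski2urt1dcl2.123 listed 942 higher and 809 lower, and 547 higher and 463 lower loci. Of 17 PPR genes 12 rose in each (adjusted Fisher's exact p = 1.4e-16 and 6.1e-20), and 11 and 12 of 86 conserved microRNA targets (3e-06 and 3e-10). AGO1 was at 2.00 and 1.85, HEN2 at 1.72 and 1.74, TAS3C at -1.34 and -1.04 and the snoRNA locus AT4G07635 at -5.07 in both, in the authors' deposited table. URT1 was at -1.74 and -1.51 in the authors' deposited table. HSP90.1 and HSP101 were at 9.99 and 7.80 in the former and at 8.96 and 6.51 in the latter in the authors' deposited table. The histone list held 5 higher genes in the former and 3 in the latter (adjusted Fisher's exact p = 0.0054 and 0.031), against 41 in rrp4-2/urt1-1/heso1-4, and the difference between lines was not tested.

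Of the 14888 loci, 8465 were listed in 1 line and 2 in all 13. Mitochondrial loci were few outside rrp4urt1dcl2het: 2 lower in ski2-5, 1 higher and 1 lower in rrp4-2, 5 higher and 1 lower in rrp4-2/urt1-1/heso1-4 and 2 each way in rrp4urt1dcl2.B9.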
